A study of Mus musculus with 8 samples.

How the data were processed

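RNA was measured in CD4 single-positive (CD4SP) thymocytes, the CD4-lineage T cells of the thymus that have passed selection, sorted from C57BL/6 mice. Per the labels' protocols, the sorted cells were lysed and RNA was purified with a column kit for small samples. Nanogram amounts of RNA were amplified by a whole-transcriptome method, labelled with biotin and hybridised to Mouse Gene 2.0 ST arrays, as the description label names the array. The 8 arrays fall into 2 genotypes, 4 wild-type (WT) and 4 labelled as knockout of Pggt1b (KO), 1 array per sample. Replicates were numbered within a genotype in the order of deposit, and these numbers pair no samples. No batch, hybridisation date or litter is given in the sources used here.

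The deposited values are log2 intensities per gene-level probe set, made by the authors with RMA (background correction, quantile normalization over the arrays and a median-polish summary) in Affymetrix Expression Console 1.1, per the submitters' processing notes. The genome build, the annotation release and any filter applied before deposit are not given in the sources used here. No detection p-values were used. The table held 41345 probe sets with values from 2.14 to 13.56, and the array medians lay between 5.52 and 5.59. Amplification of small RNA amounts and background signal compress differences of weakly expressed genes, and the number of arrays limits the precision.

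Probe sets were named through a platform annotation, which can be old. It lists 25335 of the probe sets with a gene, 23521 of them with 1 symbol and 1814 with several, while 16010 are not listed and stay unnamed here. Only probe sets with 1 symbol were tested. They stand for 22180 genes, of which 1082 have more than 1 probe set, and each such gene was represented by the probe set with the highest mean over all 8 arrays. A gene entered the test where this mean was at or above the median of all probe set means, a log2 value of 5.56. That left 11585 genes and set aside 10595. A RefSeq gene table of the assembly GRCm38.p6 served only to find which genes neighbour Pggt1b.

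KO was compared with WT by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with genotype as the only term and Benjamini-Hochberg adjustment over the tested genes. Every adjusted p printed for a gene comes from this fit unless another setting is named, and a gene is called changed at an adjusted p under 0.05. Differences are KO minus WT on the log2 scale, with the standard error (SE) of the fit. A second count also required a fold of at least 1.5.

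A total of 25 gene lists were fixed before the data were examined. They hold mevalonate and sterol synthesis, prenylation enzymes, GTPase effectors and actin regulators of T cell migration, SRF and MRTF targets, trafficking receptors, mature single-positive thymocyte genes, recently selected and TCR-induced genes, double-positive thymocyte genes, the type I interferon response, NF-kB targets, cell cycle, p53 targets, the BCL2 family, gamma-chain cytokine signalling, MYC and ribosome biogenesis, the integrated stress and unfolded protein response, and the dissociation and heat-shock response. The others hold markers of regulatory T cells, innate-like and effector T cells, the CD8 lineage, B cells, myeloid and dendritic cells, thymic epithelial, stromal and endothelial cells, and erythroid cells. Results of 1 further list are not given, although it counts among the lists tested. Each list with at least 3 tested members was tested with limma's camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over 24 lists. Camera compares the change of a list's members with that of the other tested genes, not with 0. The median change of all tested genes was -0.030 log2, so camera's direction can differ from the sign of a list's mean or median. The camera test was repeated with the correlation estimated from the data and on ranks. The exact permutation test of each list's mean per array was added after the data were seen.

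The rule for named genes was also fixed beforehand. It takes Pggt1b, and the 12 largest rises and 12 largest falls among called genes whose KO arrays all lie on one side of all WT arrays, leaving out predicted genes, small RNA genes and antigen receptor segments, which are given as counts. Of each list it takes up to 4 tested members, called ones first and then by p, with no limit for the mature single-positive, trafficking and mevalonate lists.

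The alternatives were no intensity filter, a mean log2 of at least 6, the mean of a gene's probe sets, a second quantile normalization, centring of each array on its median, array weights, the sample number in the titles as a covariate, an intensity trend with a robust prior, all probe sets whether named or not, an adjusted p of 0.01, a fold of at least 2, both other forms of camera, and leaving out each array in turn. Added after the data were seen were the mean of Hspa1a and Hspa1b as a covariate, leaving out KO replicates 1 and 2, leaving out each other pair of KO arrays (for the counts of changed genes), leaving out WT replicates 2 and 3, and adjustment without the cell cycle list. For genes named after their values were seen, the arrays were left out in turn only after that, and the separate probe sets of Ighm were examined then as well. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

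The gene test was first tested on simulated data with the means and spreads of the 11585 genes and 200 changed genes. For KO against WT it recovered 49.3% of the changes of 0.3 log2, 89.6% of those of 0.6 log2 and 98.5% of those of 1 log2. Of 168 simulated calls, 5.95% were false. Camera found a simulated list moved by 0.3 log2 and called 0 of the other simulated lists. The simulated genes varied independently, whereas the cell cycle list, for example, had an estimated correlation of 0.57. The simulation therefore does not measure false list calls in the real data. Its rates of recovery and of false gene calls do not carry over either. It changed 200 genes, while 1503 were called in the real data, and the adjustment depends on how many genes change.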

Results

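The study addressed how protein geranylgeranylation, the attachment of a lipid made by the mevalonate pathway to small GTPases, bears on the egress of thymocytes. Pggt1b encodes the catalytic beta subunit of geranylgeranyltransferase I, the enzyme that attaches this lipid to its protein substrates. Gene expression was measured in sorted CD4SP thymocytes on 8 arrays, 4 of WT and 4 of KO cells. Pearson correlations across tested genes, which are not independent replicates, were 0.990 to 0.995 between arrays of a genotype and 0.985 to 0.990 between genotypes. These ranges overlapped. WT replicate 1 correlated at 0.99009 with WT replicate 4 and at 0.99039 with KO replicate 3. The first principal component, with 43.0% of the variance, separated the genotypes, and the second held 15.8%. No 2 arrays held identical values. Nothing in the labels says that the replicates came from separate animals, so p-values measure only the spread between these samples.

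The targeted gene was examined first in every array. Pggt1b stood at log2 values of 8.36, 8.38, 8.29 and 8.36 in the WT arrays and at 7.89, 7.57, 7.69 and 7.86 in the KO arrays. It fell from 8.35 ± 0.040 to 7.75 ± 0.15 (SD, n = 4 per genotype), a log2 difference of -0.59 ± 0.072 SE, by which its level fell by 33.7% (limma, Benjamini-Hochberg adjusted p = 0.00141). All KO arrays lay below all WT arrays. The probe set is a summary over the transcript, and which part of the gene was deleted is not given in the sources used here, so a value from it does not measure the loss of the protein.

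The comparison of KO with WT asks which transcripts differ when Pggt1b is targeted. Among genes other than predicted, small RNA and receptor segment genes the largest rises were Slc28a2b, of a family of nucleoside transporters, at 8.20-fold (log2 3.04 ± 0.15 SE), Klrd1, the CD94 subunit of a lectin-like receptor of natural killer and T cells, at 7.49-fold, and Pde2a, a cyclic nucleotide phosphodiesterase, at 7.16-fold. The WT mean of Klrd1, 5.03 log2, and that of Chil5, 5.46, lay below the intensity filter of 5.56, so the size of these folds depends on background signal and is not firm. Cd55, which restrains complement, rose 4.12-fold. Chil5, Cdc25b, Sidt1 and Lncpint rose between 3.19-fold and 2.93-fold, and Usp28, Rhob, Clcf1 and Dapl1 between 2.52-fold and 2.40-fold. The largest fall was that of the matrix metalloproteinase Mmp9, 3.05-fold lower in KO (log2 -1.61 ± 0.26 SE). Apol9b, the prolyl hydroxylase Egln3, the costimulatory ligand Cd86 and the peptide transporter Slc15a1 fell between 2.19-fold and 2.07-fold. H2-DMb2, Ccr8, Dtl, Cd44, Tmem35a, Tspan9 and the Rac exchange factor Tiam1 fell between 1.98-fold and 1.87-fold. Adjusted p for these 24 genes ran from 1.38e-06 for Pde2a to 0.0102 for Apol9b (limma, Benjamini-Hochberg).

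Of 11585 genes tested, 1503 changed, 515 higher and 988 lower in KO, so that 34.3% of the calls were higher. The share depended on the scaling, on the probe sets tested, on the threshold and on the arrays used. With each array centred on its median 383 genes were higher and 1321 lower (22.5% higher). Over all probe sets, named or not, 490 were higher and 506 lower (49.2% higher). At an adjusted p under 0.01 in the main scaling 206 genes were higher and 240 lower (46.2% higher). The share was 52.8% without KO replicates 1 and 2 and 50.9% without WT replicates 2 and 3. At least 1.5-fold changes were found for 183 genes, 88 higher and 95 lower, and at least 2-fold changes for 28, 23 higher and 5 lower. In 1407 of the 1503 changed genes all KO arrays lay on one side of all WT arrays. Among all tested genes 20.3% were separated in this way, against 2.86% by chance for 4 against 4. The changed genes included 70 predicted genes, 46 of them higher, 13 small RNA genes, 12 of them higher, and 2 antigen receptor segments, both lower. The count of changed genes fell to 813 without KO replicate 1, 887 without WT replicate 2, 930 without WT replicate 3 and 966 without KO replicate 3. It was 874 with the heat-shock level as a covariate, 254 without KO replicates 1 and 2, and 295 without WT replicates 2 and 3.

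**Figure D1:**
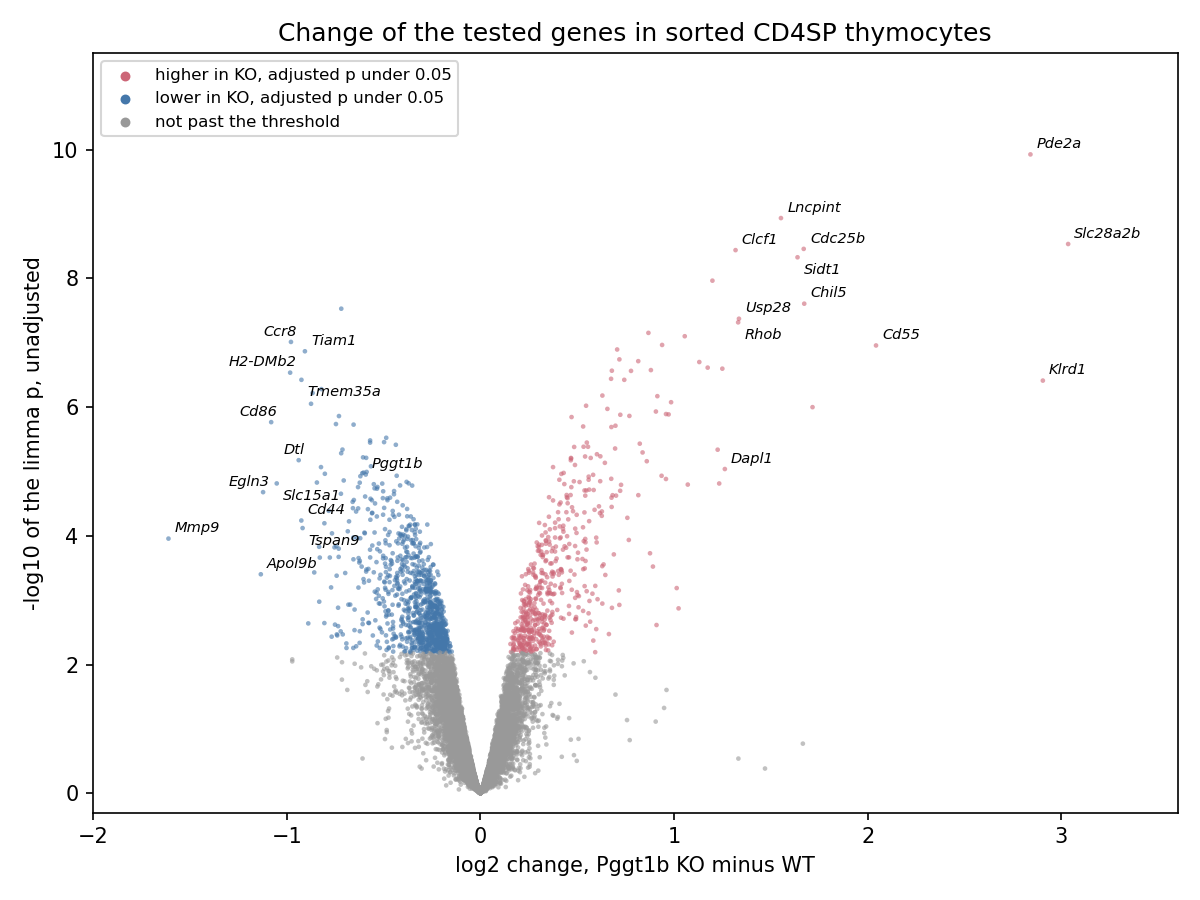
Log2 change of each tested gene (KO minus WT, horizontal) against -log10 of its unadjusted limma p (vertical), with 515 genes higher in KO and 988 lower at an adjusted p under 0.05 in colour. Slc28a2b, Klrd1 and Pde2a lie farthest to the right, at log2 changes of 3.04, 2.90 and 2.84, and Mmp9 farthest to the left of the named genes, at -1.61.

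As a list, genes that rise as single-positive thymocytes mature were higher in KO, though not in every member. Of 18 tested members of this list 9 rose and 0 fell (10 rose when adjusted over the list alone). Besides Cd55 and Dapl1 they were Tnfrsf26 at 1.96-fold, Klf2, a transcription factor that drives S1pr1, at 1.60-fold, Ms4a4b at 1.46-fold, Ms4a6b at 1.29-fold, S1pr1, the sphingosine 1-phosphate receptor required for thymic exit, at 1.24-fold (log2 0.31 ± 0.054 SE), Itgb7 at 1.17-fold and Gimap3 at 1.14-fold. Il7r stood 1.13-fold higher with an adjusted p of 0.110, and Foxo1 and Slfn1 differed by 0.02 and 0.0041 log2. Gimap4, Gimap6 and Ifngr1 stood at -0.07, -0.07 and -0.11 log2 and were not called. The list mean was 0.38 log2 higher in KO and the median 0.18 (camera adjusted p = 2.64e-07, and adjusted p = 0.0220 with an estimated correlation). The call of Gimap3 ended without KO replicate 1, 2 or 3 or WT replicate 3 or 4 (adjusted p up to 0.0689), and that of Itgb7 without WT replicate 2 or 3 or KO replicate 2 or 4 (adjusted p up to 0.0691).

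Genes induced by T cell receptor signalling and recent selection were lower in KO. Of 22 tested members 12 fell and 1 rose (18 fell and 1 rose when adjusted over the list alone). Cd24a, a surface protein lost with maturation, fell 1.69-fold (log2 -0.75 ± 0.13 SE), the transcription factor Irf4 1.48-fold, the inhibitory receptor Pdcd1 1.46-fold and the nuclear receptor Nr4a2 1.37-fold. The member that rose was Id3, by 0.26 log2 (adjusted p = 0.0475), named after its value was seen, and this call ended when any single array was left out (adjusted p from 0.0512 to 0.119). Averaged over its members the list stood at -0.29 log2 (camera adjusted p = 1.09e-06, but adjusted p = 0.441 with an estimated correlation). The double-positive thymocyte list, the stage before, had 1 member that rose and 2 that fell of 16 (3 fell and 1 rose when adjusted over the list alone). Its mean was -0.12 log2 and its camera adjusted p was 0.281, or 0.0438 with no intensity filter. This mean rests mostly on KO replicates 2 and 4, at -0.27 and -0.15 log2 from the WT mean, while KO replicates 1 and 3, at -0.04 and -0.01, lay within the WT range, and without KO replicate 2 it was -0.07. Pdlim4 rose 1.77-fold, Bcl6 fell 1.31-fold and Cd8a fell 1.67-fold. The call of Cd8a ended without WT replicate 2 or 3 or KO replicate 2 or 4 (adjusted p up to 0.0891) and that of Bcl6 without WT replicate 2 (adjusted p = 0.0504).

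Proliferation genes were lower in KO. Of 24 tested cell cycle members 13 fell and 0 rose (23 fell when adjusted over the list alone). The count of falls over all genes was 5 without WT replicate 2 or 3, 6 without KO replicate 1 or 2, 7 without KO replicate 3, 8 without WT replicate 1, 15 without KO replicate 4, 18 without WT replicate 4, and 5 with the heat-shock level as a covariate. The replication helicase subunits Mcm5 and Mcm2 fell 1.46-fold and 1.35-fold, the ribonucleotide reductase subunit Rrm1 1.33-fold and the transcription factor E2f1 1.44-fold. Over all tested members the mean was -0.46 log2 (camera adjusted p = 1.45e-09, but adjusted p = 0.608 with an estimated correlation). The list means of the arrays overlapped between the genotypes, from 8.07 to 8.51 in WT and from 7.76 to 8.09 in KO (two-sided exact permutation p = 0.0571).

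**Figure D2:**
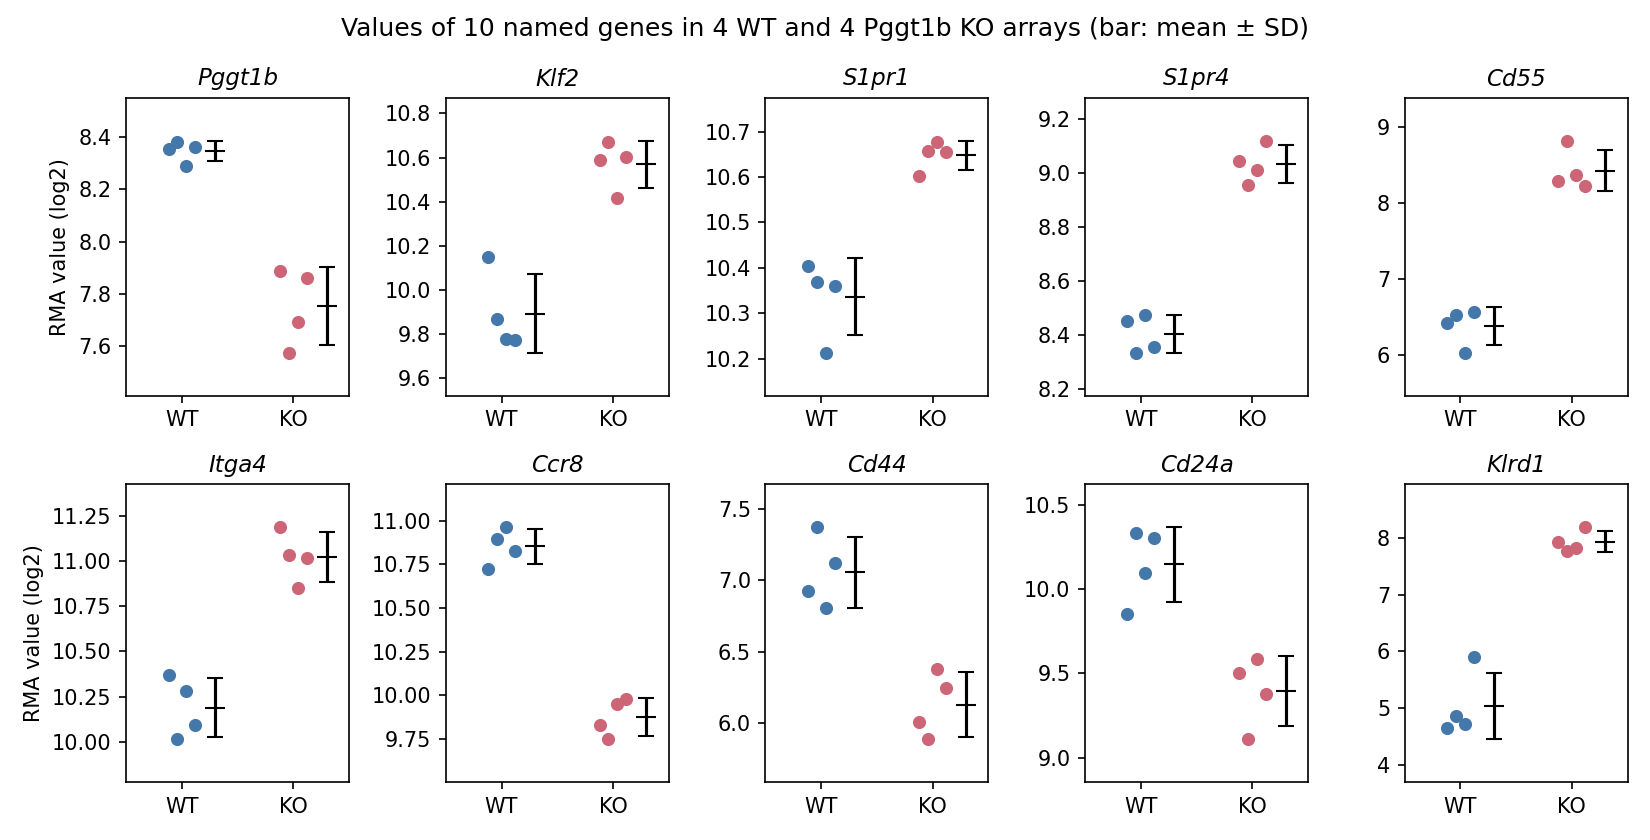
RMA values (log2, vertical) of 10 genes in each of the 4 WT and 4 KO arrays (points), with the mean and SD of each genotype beside them, each panel on its own scale. Pggt1b lies at 8.35 in WT and 7.75 in KO, S1pr1 at 10.34 and 10.65, Cd55 at 6.39 and 8.43, and Ccr8 at 10.85 and 9.88.

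Receptors of thymocyte trafficking changed in both directions. Of 20 tested members 5 rose and 6 fell (6 rose and 9 fell when adjusted over the list alone). The integrin subunits Itga4 and Itga6 rose 1.79-fold and 1.71-fold, the sphingosine 1-phosphate receptor S1pr4 rose 1.55-fold, and S1pr1 and Itgb7 rose as above. The chemokine receptor Ccr8 fell 1.97-fold, the hyaluronan receptor Cd44 1.90-fold, the chemokine receptor Ccr4 1.37-fold, the integrin subunit Itgb1 1.30-fold, the semaphorin receptor Plxnd1 1.27-fold and the integrin subunit Itgal 1.20-fold. Ccr7 differed by 0.03 log2 (adjusted p = 0.779), Ccr9 by -0.31 (adjusted p = 0.101) and Cxcr4 by 0.76 (adjusted p = 0.217). The mean of the members was -0.04 log2 and their median -0.12, while camera put the list upward (adjusted p = 0.856). The calls ended of Ccr4 when any single array other than WT replicate 1 or KO replicate 3 was left out (adjusted p up to 0.102), of Itgb7 as above, and of Itgal without KO replicate 1 or WT replicate 2 (adjusted p = 0.0542 and 0.0506).

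The pathway of geranylgeranylation was tested in 2 lists. Of 19 mevalonate and sterol synthesis genes 1 fell, Mvd, the decarboxylase of the pathway, by 1.18-fold (0 when adjusted over the list alone). The count of falls was 4 with each array centred on its median or with array weights, 2 at a mean log2 of at least 6, with the sample number as a covariate or without WT replicate 1, and 0 with no intensity filter. The call of Mvd ended when any single array other than WT replicate 4 was left out (adjusted p from 0.0580 to 0.120). Dhcr7 and Mvk stood at -0.20 and -0.23 log2 with adjusted p of 0.0549 and 0.0594, and Srebf2 at 0.09 (adjusted p = 0.355). The list mean was -0.10 log2 (camera adjusted p = 0.219), and the list passed the threshold without KO replicate 2 (adjusted p = 0.0477), without KO replicates 1 and 2 (adjusted p = 0.0347) and with no intensity filter (adjusted p = 0.0372). Among 13 prenylation enzymes only Pggt1b changed (1 fell when adjusted over the list alone), the list mean was -0.04, its median 0.03 and its camera adjusted p 0.928.

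Counts for migration machinery and its transcriptional targets depended on the scaling. Of 25 effectors and actin regulators of migration Tiam1 fell and Wasf2 rose 1.13-fold (3 rose and 3 fell when adjusted over the list alone). With each array centred on its median 0 rose and 4 fell, and after a second quantile normalization 2 rose and 1 fell. The call of Wasf2 ended when any single array other than WT replicate 1 was left out (adjusted p up to 0.0882). Their mean of -0.05 and median of -0.02 differed in sign from camera's direction (adjusted p = 0.865). Of 19 SRF and MRTF targets the immediate-early gene Egr1 fell 1.28-fold and Srf itself 1.16-fold (4 fell when adjusted over the list alone). The count of falls was 5 with each array centred on its median or with the sample number as a covariate, 4 after a second quantile normalization and 1 with no intensity filter. The call of Srf ended without KO replicate 1 or 3 or WT replicate 2 or 3 (adjusted p up to 0.0706). Over all tested members the mean was -0.07 (camera adjusted p = 0.281).

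Means of the interferon and NF-kB lists were lower in KO, though most members were not called. Of 19 interferon response genes 4 fell (8 when adjusted over the list alone), namely Isg20 at 1.37-fold, Isg15 at 1.46-fold, Rtp4 at 1.43-fold and the RNA sensor Ifih1 at 1.26-fold. The count of falls was 1 without KO replicate 3, 2 without WT replicate 4, 10 without KO replicate 4, 8 with each array centred on its median, 9 with the sample number as a covariate, and 1 with the heat-shock level as a covariate. The mean of the members was -0.31 (camera adjusted p = 0.00268, but adjusted p = 0.654 with an estimated correlation). Without KO replicates 1 and 2 its adjusted p was 0.0744. Its array means overlapped between the genotypes, from 9.15 to 9.48 in WT and from 8.77 to 9.22 in KO. Of 18 NF-kB targets 6 fell (7 when adjusted over the list alone), led by the cytokine Tnf at 1.71-fold and the receptors Tnfrsf4 at 1.40-fold and Tnfrsf18 at 1.25-fold. Without WT replicate 2 or KO replicate 2 or with no intensity filter the count was 3, and without WT replicates 2 and 3 it was 0. The list mean was -0.17 (camera adjusted p = 0.0401, but adjusted p = 0.638 with an estimated correlation). The list's call ended without WT replicate 1 (adjusted p = 0.105), KO replicate 2 (0.0967) or WT replicate 4 (0.0820). The list's adjusted p was 0.111 after a second quantile normalization, 0.0780 with array weights, 0.0571 at a mean log2 of at least 6, 0.0548 with the heat-shock level as a covariate and 0.158 without KO replicates 1 and 2. The calls ended of Rtp4 without KO replicate 1, 2 or 3 or WT replicate 3 or 4 (adjusted p up to 0.0757), of Isg15 without KO replicate 3 or WT replicate 4 (up to 0.0621) and of Ifih1 without KO replicate 3 (0.0517).

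Survival and cytokine genes moved in both directions. Of 16 p53 targets 3 rose and 1 fell (the same numbers when adjusted over the list alone), with Bbc3, which encodes the pro-apoptotic protein PUMA, at 1.64-fold and Sesn1 at 1.40-fold, a list mean of 0.03 and a camera adjusted p of 0.380. Pmaip1, which encodes the pro-apoptotic NOXA, rose 1.26-fold and the death receptor Tnfrsf10b fell 1.32-fold. The call of Pmaip1 ended without KO replicate 1, 3 or 4 (adjusted p up to 0.0566), and that of Tnfrsf10b when any single array other than WT replicate 1 or KO replicate 1 or 3 was left out (up to 0.0685). Of 12 BCL2 family members 2 rose and 1 fell (2 and 2 when adjusted over the list alone). The pro-apoptotic Bak1 fell 1.34-fold while Bbc3 and Pmaip1 rose, and the mean of 0.02 and the median of -0.01 differed in sign (camera upward, adjusted p = 0.720).

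Of 19 gamma-chain cytokine genes 2 rose and 2 fell (2 and 2 when adjusted over the list alone). The kinase Pim1 rose 1.98-fold and the receptor Il6ra 1.44-fold, while Gfi1 and Il2rb fell 1.33-fold and 1.40-fold, with a camera adjusted p of 0.380. Of 20 MYC and ribosome biogenesis genes 2 fell (2 when adjusted over the list alone), Tfrc and Odc1, by 1.24-fold and 1.17-fold. The call of Tfrc ended when any single array other than WT replicate 1 or 4 was left out, and that of Odc1 for any other than WT replicate 2 or KO replicate 2 (adjusted p up to 0.0712 and 0.0777). Averaged over its members the list stood at -0.07, with a camera adjusted p of 0.293. Of 15 stress response genes 1 rose and 4 fell (1 and 5 when adjusted over the list alone, and 2 falls over all genes without WT replicate 1 or 4 or KO replicate 1, 2 or 3), with Sdf2l1 and Psat1 lower by 1.45-fold and 1.43-fold, a list mean of -0.16 and a camera adjusted p of 0.134, 0.0167 with no intensity filter or 0.0465 without WT replicates 2 and 3. Trib3 rose 1.25-fold and Phgdh, of serine synthesis, fell 1.29-fold. The remaining fall was that of Ddit3, by 0.25 log2 (adjusted p = 0.0494), named after its value was seen, and its call ended when any single array other than WT replicate 3 or KO replicate 4 was left out (adjusted p up to 0.128). The call of Trib3 ended when any single array other than WT replicate 3 or 4 or KO replicate 3 was left out (adjusted p up to 0.0727), and that of Phgdh for any other than WT replicate 2 or 3 or KO replicate 4 (up to 0.0649).

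Heat-shock genes varied between arrays within both genotypes. The mean of Hspa1a and Hspa1b was 5.27, 6.36, 8.58 and 6.74 log2 in the WT arrays and 10.34, 9.79, 4.57 and 8.25 in the KO arrays. Hspa1a stood 1.67 log2 higher in KO with an adjusted p of 0.363. Of 18 dissociation and heat-shock genes 2 rose and 2 fell (3 and 2 when adjusted over the list alone). Without KO replicate 3 the rises were 4 of 19 tested, and with the heat-shock level or the sample number as a covariate 1. Klf6, a transcription factor, rose 2.08-fold and the signalling regulator Rgs1 fell 1.49-fold, besides Egr1, which fell. Jun rose 1.88-fold, a call that ended when any single array other than WT replicate 2 or 4 or KO replicate 3 was left out (adjusted p up to 0.0792). Over all tested members the mean was 0.26 (camera adjusted p = 0.219), and the list passed the threshold without KO replicate 3, at a mean of 0.44 (adjusted p = 0.00495). Without KO replicate 1 the mean was 0.14 (adjusted p = 0.308), and with the heat-shock level as a covariate 0.03 (adjusted p = 0.681). With the heat-shock level as a covariate the mature, recently selected and cell cycle lists stood at 0.39 ± 0.036, -0.28 ± 0.050 and -0.44 ± 0.14 log2 (SE between arrays).

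Markers of other cells in the thymus were measured beside these groups. Of 14 regulatory T cell markers 5 fell and 0 rose (9 fell when adjusted over the list alone), namely Tnfrsf4, Tnfrsf18, Il2rb, Capg by 1.22-fold and Gpr83 (adjusted p = 0.0436). The last was named after its value was seen, and its call ended when any single array other than WT replicate 1 or KO replicate 3 was left out (adjusted p up to 0.0980). The mean of the members was -0.25 (camera adjusted p = 0.00306, but adjusted p = 0.608 with an estimated correlation). Of 12 innate-like and effector T cell markers 6 fell and 1, Klrd1, rose (8 and 1 when adjusted over the list alone), and Nkg7, a cytotoxic granule protein, fell 1.78-fold. The count of falls was 2 without KO replicate 1 or 3 3 without WT replicate 2 or KO replicate 2 or 4, and 4 or 5 without any other array. The list mean was -0.15 and the median -0.37 (camera adjusted p = 0.0361, but adjusted p = 0.638 with an estimated correlation). Klrd1, at 2.90 log2, raises the mean. Without WT replicate 4 this list had a mean of -0.05 and an adjusted p of 0.0820, and without WT replicate 1 a mean of -0.23 and an adjusted p of 0.00977. Its adjusted p was 0.0528 at a mean log2 of at least 6, 0.0586 after a second quantile normalization, 0.0825 with each array centred on its median and 0.0743 without KO replicates 1 and 2. The other natural killer cell markers, with Klrd1 2.90 log2 higher, had a median change of -0.07 log2.

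Of 9 CD8 lineage markers 2 rose, Klrd1 and the pore-forming Prf1 at 1.51-fold, and 2 fell, Nkg7 and Cd8a (3 and 3 when adjusted over the list alone). Their mean was 0.18 and their median -0.13, with camera upward (adjusted p = 0.785). Of 5 tested B cell markers the immunoglobulin heavy chain gene Ighm rose 1.60-fold (1 rose when adjusted over the list alone). Ighm has 7 probe sets, 3 of them above the intensity filter. Of these the brightest, which stands for the gene, was higher in KO by 0.68 log2, the next by 0.34 ± 0.15 (SE), and the third differed by -0.20 ± 0.11. With the mean of all 7, in which 4 lie below the filter, the difference was 0.06 log2 (adjusted p = 0.697), 0 B cell markers rose, and the list mean was 0.015. In the main setting the list had a mean of 0.14 and a camera adjusted p of 0.191, while the other B cell markers had a median change of 0.016 log2 without the intensity filter. Without WT replicate 3 this list passed the threshold (adjusted p = 0.0495). Of 8 tested myeloid and dendritic cell markers 0 changed by limma (0 when adjusted over the list alone), although Itgam, 0.26 log2 higher in KO, had an unadjusted p of 0.0317 and an adjusted p of 0.131, or 0.0189 without WT replicate 1. Their mean and median were -0.02 and -0.03 with camera upward (adjusted p = 0.785). Of 6 tested epithelial, stromal and endothelial markers Pecam1 rose 1.18-fold (1 when adjusted over the list alone), a call that ended when any single array other than WT replicate 1 or KO replicate 4 was left out (adjusted p up to 0.0770), and the camera adjusted p was 0.370. No erythroid marker could be tested, since 3 lay below the intensity filter and 9 had no probe set with a single symbol.

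In total 7 of 24 lists, 1 of which is not reported by name and did not shift, passed the threshold of camera, 1 upward and 6 downward, and by ranks also 7. With 6 of the 8 arrays, without KO replicates 1 and 2 or without WT replicates 2 and 3, the mature list had 4 rises in both, the recently selected list 2 and 3 falls, and the cell cycle list 3 falls in both. With an estimated correlation 1 list, the mature single-positive genes, passed. Of the 35 splits of the arrays into 4 and 4, 6 gave at least as many lists, the real one included, and 1 other split gave 9. By an exact two-sided permutation test of the list mean per array, for which 4 against 4 allows no p below 0.0286, 6 lists reached that value, the mature, recently selected, NF-kB, regulatory T cell, MYC and stress response lists (Benjamini-Hochberg adjusted p = 0.114 over 24 lists). The interferon and innate-like lists gave p of 0.0571 and 0.314, the latter from a mean that includes Klrd1 at 2.90 log2.

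**Figure D3:**
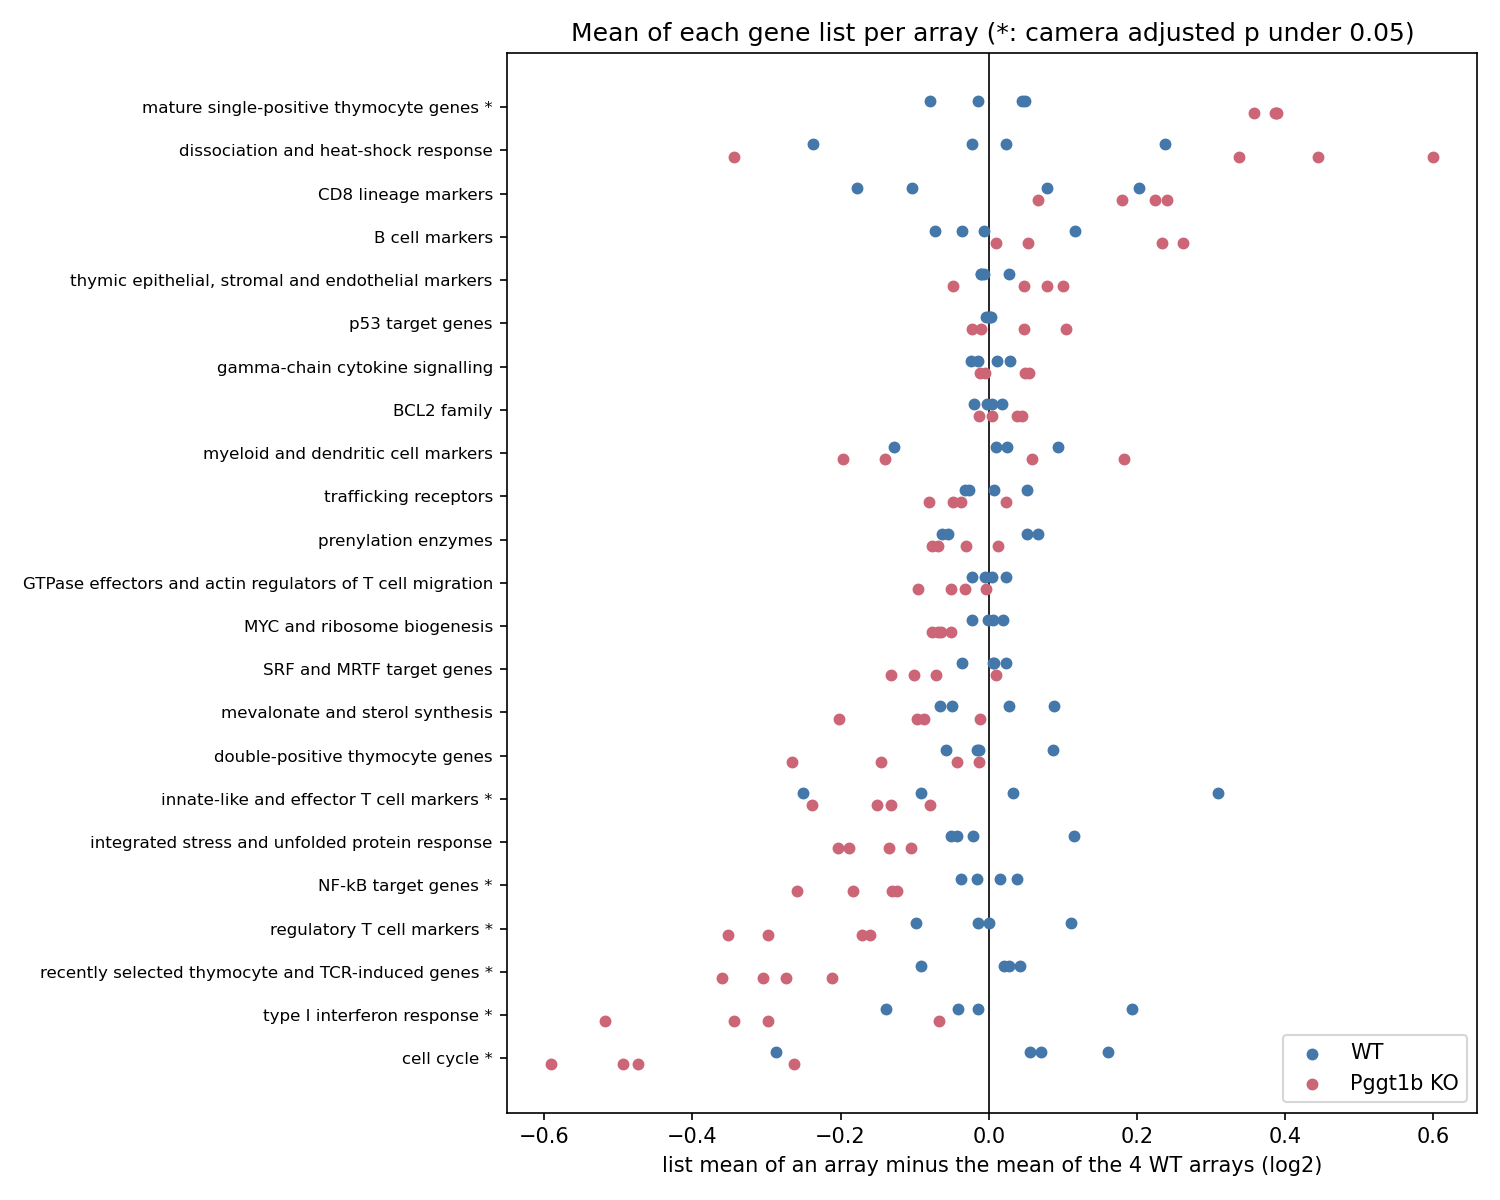
Mean of each reported gene list in each of the 4 WT and 4 KO arrays, as the difference from the mean of the WT arrays (log2, horizontal), with 1 row per list and lists past the camera threshold marked by a star. The mature single-positive list lies between 0.36 and 0.39 in the KO arrays, while the dissociation and heat-shock list runs from -0.24 to 0.24 in WT and from -0.34 to 0.60 in KO.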

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

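The tests with the heat-shock level, of the double-positive share, of the late-stage share and of B and natural killer cells were chosen only after the result was seen. The splits of the arrays were set beforehand.

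Of the 35 splits of the arrays into 4 and 4, 1, the real one, gave 1503 changed genes, and the highest other split gave 1. For changes of at least 1.5-fold 1 split, again the real one, gave 183 genes and the highest other split 1. Both counts argue against chance but do not exclude it. A share of 1 in 35 is the smallest that these splits allow, and every other split mixes the genotypes. For the number of shifted lists chance cannot be excluded, since 6 of 35 splits gave at least the 7 lists of the real one and the highest other split gave 9.

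In 20 of 340 groups of 4 arrays 1 array lay far from the other 3, where chance gives about 17. The groups were those of the named genes and of the list means. In WT replicate 4 these were Klrd1 at 5.90 log2, Fdps at 9.51, Sqle at 7.03, Slfn2 at 11.12, Isg15 at 6.65 and Psat1 at 8.98, all above the other WT arrays, and Pmaip1 at 5.55, below them. In WT replicate 2 Slc28a2b stood at 7.55 and Egln3 at 8.67, above the others. In WT replicate 1 Fdft1 stood at 8.96 and Gfi1 at 8.26, below the others. In WT replicate 3 Lss stood at 7.11 and Nfkbie at 8.69, below the others, and H2-Aa at 5.83, above them. Among KO arrays Plxnd1 stood at 9.30 in replicate 4 and Ccr9 at 9.99 in replicate 3, above the others, and Phgdh at 7.53 in replicate 2, below them. Relative to the WT mean, the mature single-positive list stood at 0.36 in KO replicate 3, where the other KO arrays lay at 0.39. The recently selected list stood at -0.091 in WT replicate 1 and the epithelial, stromal and endothelial list at 0.027 in WT replicate 3.

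The mature single-positive list was higher in KO while the recently selected and cell cycle lists were lower. Handling of the cells, as read by Hspa1a and Hspa1b, is argued against as the whole source, since 3 of 3 lists kept at least 96.3% of their difference with that level as a covariate. A lower share of double-positive cells in the KO sort stays open: their list was lower by less than the recently selected list, by 0.171 ± 0.042 log2 (SE between arrays), but its members went both ways and the SE between members was 0.091. A larger share of late-stage cells within the CD4SP gate may account for the pattern, and a change in each cell may too. The 9 mature list members that rose, with 0 that fell, leave both open, because bulk RNA does not separate the share of a stage from the level per cell.

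Ighm, Klrd1 and H2-Ob were higher in KO, by 0.68, 2.90 and 0.96 log2, where the 2 other Ighm probe sets above the intensity filter stood at 0.34 ± 0.15 and -0.20 ± 0.11 (SE), and the mean of all 7, 4 of them below the filter, at 0.06 (adjusted p = 0.697). B cells passing the CD4SP gate could bring Ighm and H2-Ob, and natural killer cells Klrd1, but they would bring their other transcripts too. Only Ighm and Klrd1 were set against such transcripts. The 11 other B cell markers had a median change of 0.016 ± 0.048 log2 (SE between markers, not arrays), with Ebf1 the highest at 0.18, and 4 of them lay above the intensity filter. The 15 other natural killer cell markers, 12 of which other lists hold, had a median of -0.070 ± 0.10 log2 (SE between markers), with Prf1 the highest at 0.59, and 7 lay above the filter. The natural killer value argues against such cells as the source of Klrd1 and the B cell value against B cells as that of Ighm, and the genotype stays open as an explanation that was not tested apart from them.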

How the results depend on the processing

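The heat-shock covariate, leaving out pairs of arrays (each pair of KO arrays, or WT replicates 2 and 3), and adjustment without the cell cycle list were chosen after seeing the data, while all other alternatives were planned. Pggt1b was lower in KO and called under every alternative that tested it, from -0.64 to -0.53 log2 with adjusted p up to 0.0252. The 1503 changed genes became 920 with no intensity filter and 996 over all probe sets, where more probe sets share the adjustment, and 446 at an adjusted p of 0.01. They became 874 with the heat-shock covariate (the cause was not tested), of which 833 were among the 1503. With fewer arrays they became 254 without KO replicates 1 and 2, 295 without WT replicates 2 and 3, and between 813 and 1450 when single arrays were left out. Leaving out other pairs of KO arrays gave 371 to 621. The remaining settings gave 1433 to 1776. The 183 genes changed at least 1.5-fold became 28 at a fold of at least 2, 111 without KO replicates 1 and 2, 141 to 220 without other pairs of KO arrays, and 150 to 211 without single arrays. The 7 shifted lists became 1 with an estimated correlation, which allows for genes that vary together, 10 with no intensity filter, and 5 to 8 without single arrays. The estimated correlation setting raised p for other reasons too. The mature list had an estimated correlation of -0.0034, below the preset, yet its unadjusted camera p went from 2.2e-08 to 0.00092. Calls lost under that setting are therefore not due to genes that vary together alone. The mature single-positive list was called under all 21 alternatives run for it (adjusted p up to 0.0221). The 88 called named genes include Pggt1b. Of those other than Pggt1b 63 stayed called without any single array and 35 under every alternative, and 0 reversed while called. The calls of 19 named genes ended with the heat-shock covariate (adjusted p up to 0.0979) and of 15 with no intensity filter (up to 0.0953). Weak signal over background limits what can be seen of the 10595 genes under the filter.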

Other observations

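The gene families described here were chosen after their values were seen, and so were the genes named from them. Predictions for the small RNA tests were set before those tests were run.

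Of 23 tested Dusp, Spry and Spred genes 8 fell and 0 rose, also with 0 rises under a second quantile normalization and median centring. The MAP kinase phosphatase Dusp6 fell by 0.82 log2, Dusp4 by 0.83 and Dusp5 by 0.44 (limma adjusted p = 0.000191, 0.00728 and 0.00311). The Dusp family alone, with 5 of 17 lower, did not pass camera (adjusted p = 0.320, and 0.972 with an estimated correlation). Of 12 Klf transcription factors 5 rose and 0 fell, in both other scalings as well. Besides Klf2 and Klf6 these were Klf3 at 0.87 log2, Klf7 at 0.43 and Klf13 at 0.26 (adjusted p = 6.8e-05, 0.00415 and 0.0183). The call of Klf13 ended without KO replicate 1 or 3 (adjusted p up to 0.0530), and camera gave the family an adjusted p of 0.00738, but 0.972 with an estimated correlation. Of 7 tested class II genes 1 rose and 3 fell, with H2-Oa at -0.87 log2, H2-DMb2 at -0.98, H2-DMa at -0.33 and H2-Ob at 0.96 (adjusted p = 0.000213, 0.000125, 0.0190 and 0.00153). H2-Aa, H2-Ab1 and H2-Eb1 were not called (adjusted p = 0.772, 0.566 and 0.421), the call of H2-DMa ended without WT replicate 2 or 3 or KO replicate 3 (adjusted p up to 0.0522), and no set test was run. Of 21 tested interleukin receptor genes 2 rose and 4 fell, and the receptor chains of interleukin 12, Il12rb1 and Il12rb2, fell by 0.59 and 0.74 log2 (adjusted p = 0.00980 and 0.0104).

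Among 193 families of symbols with at least 8 tested members 9 shifted by camera, and all had an adjusted p of 0.972 with an estimated correlation. The replication helicase family Mcm had 6 of 10 members that fell, the mitochondrial ribosomal family Mrpl 6 of 43, and the proteasome families Psmd and Psmb 4 of 14 and 5 of 10. The falls of Mrpl depended on the scaling, with 11 after a second quantile normalization and 11 with each array centred on its median. Those of Mcm were 6 and 8, of Psmd 4 and 5 and of Psmb 5 and 5 in these scalings, and 0 members of the 4 families rose in any of the 3. Of the 50 tested genes nearest to Pggt1b in the gene order of assembly GRCm38.p6, 25 on each side, 6 or 12% changed, against 13.0% of all tested genes (Fisher's exact two-sided p = 1).

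Small RNA genes were higher in KO, 131 of 194 tested, with a median change of 0.083 log2 and 12 called higher. The median was 0.060 with 9 rises after a second quantile normalization and 0.049 with 5 rises with each array centred on its median. A shift shared by named genes of like intensity at large is argued against. The main-setting median lay at percentile 100 of 10000 intensity-matched random lists of such genes, whose central range was -0.053 to -0.0076. That percentile does not measure chance, because the class was picked from this comparison and its genes can vary together. Nor does it exclude a rise shared with predicted genes. Of 299 tested genes with symbols starting in Gm 22 were called higher and 4 lower, with a median of 0.031 log2. Their camera adjusted p was 0.00257, but 0.972 with an estimated correlation. The median change of all probe sets was 0.0069 log2, against -0.030 for tested genes. The Snord, Snora and Mir families each had a camera adjusted p of 0.972 with an estimated correlation. Variation in small RNA yield unrelated to genotype may still account for the rise: all KO array means lay above all WT array means (exact permutation p = 0.0286, two-sided, the smallest possible), but the class was picked from this same comparison, which makes that test void. A difference in yield between the RNA preparations stays open too, since the 20 snoRNA host genes had a median of 0.015 ± 0.024 log2 (SE between genes, not arrays) against 0.11 ± 0.022 for 62 snoRNA genes, a value that meets neither prediction.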
